A study of Drosophila melanogaster with 4 samples.

How the data were processed

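Single-nucleus RNA sequencing was done on brains of 3rd instar larvae of Drosophila melanogaster in 4 groups, with 1 library per group. The genotypes were a control and NICD-OE, in which the intracellular domain of the Notch receptor (NICD) was expressed with Gal4 and UAS in glia positive for Eaat1. Larvae were reared at 25°C and spent 24 h in 3.5% oxygen and 96.5% nitrogen or in room air of 21% oxygen, per the labels' protocols. Nuclei were released with a lysis buffer and a Dounce homogenizer and processed with a droplet 3' kit, also per the labels' protocols; whether the barcodes fit the kit named there was not tested and is uncertain. Reads were processed with Cell Ranger 9.0.0 on genome build dm6, per the submitters' processing notes. The annotation release, the handling of introns and the use of strand in counting are not given in the sources used here.

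The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization and no filter on barcodes, as the whole numbers and the empty barcodes in the matrices show. The matrices hold 17873 features, of which 17867 were given a gene symbol from an annotation of build BDGP6.54, which also gave every coordinate printed (1-based). The 38 mitochondrial and 136 ribosomal RNA features were left out of all gene values. Nuclei were called per library by the OrdMag rule of Cell Ranger, rebuilt here (barcodes above the 99th percentile of the top barcodes divided by 10), with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. The UMI thresholds came to 747, 771, 629 and 651 in control normoxia, control hypoxia, NICD-OE normoxia and NICD-OE hypoxia, the order in which sets of 4 values are given throughout. The files held 13634, 10460, 17463 and 17440 barcodes of at least 500 UMIs. Scrublet's calculation, rewritten here, then removed 110, 59, 119 and 124 nuclei as doublets at thresholds between the 2 modes of the simulated scores (scikit-image 0.26.0), which is 0.830, 0.580, 0.693 and 0.729% of nuclei, against 10.6, 8.14, 13.7 and 13.6% expected at 0.8% per 1000 nuclei. Fewer nuclei were removed than expected in each library. The median nucleus had 2140.0, 2107, 1942 and 1870.0 UMIs and 838, 817, 816 and 819 genes, and a median 0.137, 0.129, 0.155 and 0.192% of mitochondrial UMIs, the list of mitochondrial genome transcripts. All 4 libraries were used; they held 47487114, 35770664, 56701573 and 53731551 UMIs in all, and nuclei held 68.6, 70.1, 65.6 and 68.1% of all UMIs. Barcodes of 10 to 100 UMIs gave the profile of ambient RNA, and the ambient share of a class was taken as its mitochondrial share over that of the ambient profile.

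The 57220 nuclei were clustered together (log of counts scaled to 10000 per nucleus, 2000 variable genes centred within each library, 30 principal components, 15 neighbours joined by the overlap of their neighbour sets, Leiden resolution 1; leidenalg 0.10.2, igraph 0.11.9). Genes of the mitochondrial genome, ribosomal proteins, roX RNAs, heat shock proteins and N were not used for clustering. A cluster was called X-like only from 18 marker lists; it needed at least 3 markers and 33.3% of its list raised at least 2-fold with 20 CPM added, with no other class ahead among its 10 leading genes. A glia-like cluster also needed repo raised, and neuron markers were read against the clusters that matched another list. Those thresholds were set after the clusters were seen. Of 60 clusters, 53 held at least 20 nuclei, 2 were glia-like, 28 neuron-like, 2 neural progenitor-like, 1 neuroepithelium-like and 1 hemocyte-like. The 19 unnamed clusters comprised 12 led by genes of another class, 5 with too few markers, and 2 with at least 90% of their nuclei from 1 library. Of the 12, 7 had at least 11 neuron markers raised and held 20.8, 23.0, 21.2 and 21.2% of the libraries, nuclei that the neuron-like class and its share leave out. Unnamed nuclei outside the one-library clusters made up 34.0%, 38.1%, 40.2% and 39.4% of the libraries. The glia-like nuclei were clustered again at resolution 0.5, and 5 of 12 sub-clusters were left out. Of these, 2 had leading genes of another class, 1 Lsp2, Sgs4 and Yp1 and 1 form3 and Optix. The latter had 15, 15, 57 and 25 nuclei. Another carried neuron markers, and 2 were mainly of control normoxia, 1 with 44 nuclei raised in Eaat1. The 5 held 1.06, 0.455, 0.598 and 0.545% of nuclei. They were left out after the data were seen, and whole clusters are an alternative.

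UMIs were summed per library over the glia-like, neuron-like and neural progenitor-like nuclei and given as CPM, counts per 1e6 nuclear-genome UMIs of the class. A ratio is the ratio of CPM with 0.5 count added to each sum. 4 contrasts were made per class: hypoxia against normoxia in each genotype, and NICD-OE against control in each oxygen condition; in glia-like nuclei the difference of the hypoxia contrasts was added. Levels have exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals and ratios conditional exact binomial intervals, all at 95%. With 1 library per group no test was run, no p-value is given, and no genes were counted over the genome. A gene at 0 in one library of a contrast is given as a bound, computed with a floor of 3 counts in that library. In glia-like nuclei a count of 0 allows up to 10.0, 13.8, 8.62 and 13.9 CPM, in neuron-like nuclei up to 0.166, 0.184, 0.148 and 0.128 CPM and in neural progenitor-like nuclei up to 1.90, 4.46, 1.22 and 2.95 CPM.

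The groups, comparisons, gene lists, markers and the rule for named genes were fixed before the data were examined. By that rule N, the E(spl) genes, repo, Eaat1 and w come first. In glia-like nuclei the 12 genes with the largest ratio each way per contrast follow, ranked by the interval bound nearest to 1 among genes with at least 50 UMIs in 1 of the libraries compared. In the other classes the rule takes 6 each way, for the difference of the hypoxia contrasts 8 each way (ranked by the difference less its 95% Poisson margin), and of each list its 2 highest and 2 lowest members of at least 50 UMIs. E(spl)m1, named Kaz-m1 in the annotation, was not among the genes given first; neuron-like nuclei held 1, 6, 7 and 13 UMIs of it. The 24 lists cover Notch targets, the Notch pathway, the hypoxia response, glycolysis, mitochondrial respiration, 5 lipid lists (synthesis, droplets, oxidation, transport, and sphingolipids with phospholipids, whose members were pooled as the lipid list after the data were seen), uptake of glutamate and other transmitters, heat shock, redox, the unfolded protein response with ATF4, immunity, ecdysone with insulin, the cell cycle, cell death, autophagy, neuronal transmitters, the synapse, dosage compensation, ribosomal proteins and the mitochondrial genome. A list is described by the median log2 ratio of its members with at least 20 UMIs, with the percentile of that median among 10000 random lists of equal size matched on expression in 20 bins. Ranges beside list medians hold 95% of 2000 Poisson resamples of the counts.

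The contrasts were tested on simulated Poisson counts drawn at the real means and library sizes, with 200 genes changed by known factors. In glia-like nuclei the intervals held the true ratio for 95.6%, 95.8%, 96.4% and 96.3% of unchanged genes (control hypoxia contrast, NICD-OE hypoxia contrast, NICD-OE against control in normoxia, and in hypoxia; 1128, 1296, 1296 and 897 genes run). For 9.91, 6.57, 7.39 and 6.17% of them the interval left out 1, as their true ratio moved a little with the totals. Coverage near 95% followed from drawing Poisson counts. Clumping of a gene's UMIs in single nuclei was not simulated, so the intervals can be too narrow. Genes changed 1.5-fold had an interval on the right side of 1 in 66.2%, 80.9%, 88.2% and 86.8% of cases, and genes changed 2-fold in 100%, 95.5%, 98.5% and 97.0%. In neuron-like nuclei the intervals held the true ratio for 95.4%, 95.6%, 95.6% and 95.6% of unchanged genes (7330.0, 7781, 7542 and 7748 run) and in neural progenitor-like nuclei for 95.4%, 95.1%, 95.0% and 95.6% (2828, 3811, 3712 and 2267 run). Of 88 genes named for glia-like nuclei, 52 overlap another annotated gene, 31 of them on the same strand and 42 on the other, so their counts are uncertain where reads of a neighbour could be counted with them. The Hsp70 genes, Yp1 to Yp3, Cyp4p1 with Cyp4p2, Gapdh1 with Gapdh2 and several ribosomal protein genes have close copies, and their counts are uncertain in the same way. Alternatives fixed at the start changed the calling of nuclei (at least 1000 or at least 500 UMIs, at most 2% mitochondrial UMIs, doublets kept), the clustering (no centring, resolution 2), the scaling (median-of-ratios size factors, subtraction of ambient RNA, equal weight per nucleus), the weight of glial sub-clusters, the least UMIs of a list member (100) and the count added (5). Chosen after seeing the data were the removal of the expected share of doublets, the whole glia-like clusters, shares without one-library clusters, and ratios without the nucleus that holds most UMIs of the gene in each library. Also chosen then was leaving out, in each library, the glia-like nucleus with most UMIs of ribosomal proteins, or with most UMIs of the fat body genes Lsp1alpha, Lsp1beta, Lsp1gamma, Lsp2, Fbp1 and Fbp2. The part of a gene's level that ambient RNA would bring, also added after seeing the data, is the ambient share of the class times the ambient CPM, as a percentage of the gene's CPM in the class. Parts above 100% occurred, which no real part can reach, so the estimated share is too high for those genes. The parts printed and the values with ambient RNA subtracted are therefore uncertain and can discount too much. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.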

Results

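Nuclei from larval brains were compared between control and NICD-OE animals kept in room air (normoxia) or in 3.5% oxygen for 24 h (hypoxia). In glia-like nuclei N itself was nearly level between the genotypes in normoxia, at 2466 CPM in NICD-OE and 2520.3 CPM in control, and no E(spl) gene, the classic targets of Notch, had a genotype ratio with an interval that left out 1. Most glia-like nuclei had no UMI of Eaat1, so these values need not describe the driven cells. Over all nuclei every E(spl) gene given first but E(spl)m6-BFM was higher in NICD-OE in normoxia. Genes far apart in normoxia in glia-like nuclei were others. nAChRalpha6 and Dscam4 were higher in NICD-OE and dac, Eip93F and Gs2 lower. Eip93F was also lower in progenitor-like and neuron-like nuclei, and Dscam4 higher in the former. Hypoxia went with fewer neural progenitor-like and more neuron-like nuclei in both genotypes. The 4 libraries gave 13151, 10116, 17060 and 16893 nuclei. Each group has 1 library, so no check between replicates was possible, and the intervals in parentheses cover counting error only. Glia-like sums held 298776, 217283, 347944 and 215181 UMIs.

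Neuron-like nuclei were 47.0% (46.2 to 47.9) of control normoxia and 55.6% (54.7 to 56.6) of control hypoxia, and 47.4% (46.6 to 48.1) and 53.7% (52.9 to 54.5) of the NICD-OE libraries in the same order. The rise was uneven over neuron-like clusters: the cluster led by bab1 had 7.34, 9.93, 7.57 and 10.5% of nuclei in the 4 libraries, that led by pb, with Ubx and Antp among its leading genes, 4.99, 6.37, 5.42 and 6.91%, and that led by CG4577, with abd-A, 2.16, 3.44, 1.82 and 5.30%. Others were lower with hypoxia in NICD-OE, such as those led by Drgx (4.14, 4.03, 3.51 and 2.68%) and hbn (2.02, 1.90, 1.76 and 1.23%); in control their intervals overlapped (3.81 to 4.50 and 3.66 to 4.43; 1.79 to 2.28 and 1.64 to 2.18). Over all nuclei Ubx and Antp, Hox genes active in the ventral nerve cord, were at 143, 211, 169 and 246 and 387, 488, 530.3 and 596 CPM, and whether the libraries held different amounts of nerve cord tissue was not tested. Neural progenitor-like nuclei, with markers such as mira, dpn and wor, were 6.20% (5.79 to 6.62) in control normoxia against 3.86% (3.49 to 4.25) in control hypoxia, and 8.49% (8.07 to 8.92) against 4.203% (3.91 to 4.52) in NICD-OE. Glia-like nuclei, raised in repo, made up 1.21% (1.03 to 1.41), 1.24% (1.03 to 1.47), 1.22% (1.06 to 1.395) and 0.841% (0.708 to 0.99002) (159, 125, 208 and 142 nuclei). NICD-OE hypoxia had the lowest glial share, here and in 8 other settings. Its interval lay below those of the other 3 libraries here but in only 2 of those settings, and not with whole glia-like clusters (1.21 to 1.57%) or at least 1000 UMIs (0.498 to 0.753%). The kept glial sub-clusters are named here by genes raised in their summed UMIs, and single nuclei in them can lack these genes. The sub-cluster raised in moody, Lac and Gli, genes of the blood-brain barrier, held 43, 38, 45 and 30 nuclei. That raised in the astrocyte gene alrm and in Eaat1 held 23, 19, 38 and 22, and that raised in gcm, a switch to glial fate, 50, 33, 63 and 30. The sub-cluster raised in the trehalose transporter gene Tret1-1 and ImpL2 held 17, 18, 30 and 33 nuclei. That raised in rost and the perlecan gene trol held 9, 7, 14 and 15, that raised in wrapper and Cyp4g15 9, 4, 10 and 9, and a last sub-cluster 8, 6, 8 and 3. Control normoxia also held clusters found almost only there, 9.95% of its nuclei, and without them its neuron-like share was 52.2% and its progenitor-like share 6.88%.

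**Figure D1:**
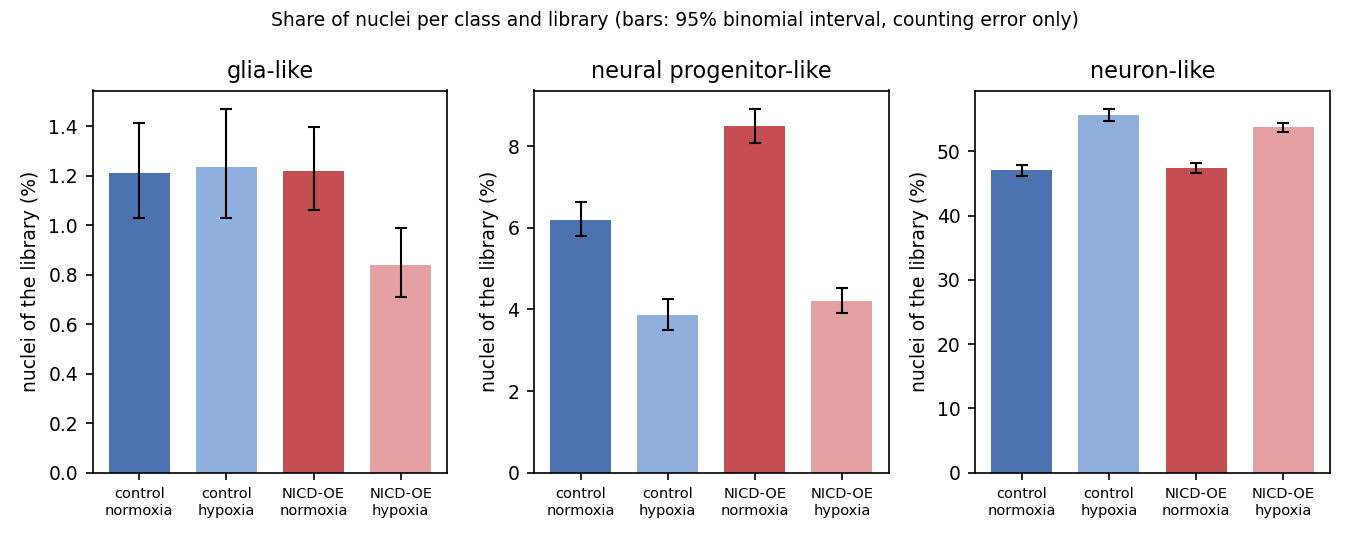
Share of nuclei (percent, vertical axis) called glia-like, neural progenitor-like and neuron-like in each of the 4 libraries, with 95% binomial intervals as bars. Neural progenitor-like nuclei were 6.20% in control normoxia and 3.86% in control hypoxia.

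N, which encodes the Notch receptor, stood at 2520.3 (2343 to 2707), 2458 (2254 to 2675), 2466 (2304 to 2637) and 1905 (1725 to 2099) CPM in glia-like nuclei. In hypoxia it was 1.29-fold (1.13 to 1.47) lower in NICD-OE than in control. Whether the transgene's transcript ends in the 3' end of N is not given in the sources used here, so N counts need not include it. E(spl)mbeta-HLH was at 224, 203, 155 and 181 CPM, E(spl)mgamma-HLH at 63.6, 64.4, 60.4 and 69.7 and E(spl)m3-HLH at 50.2, 50.6, 25.9 and 46.5. E(spl)m7-HLH was 2.32-fold (1.17 to 4.93) higher in hypoxia than in normoxia in control (110.5 against 46.9 CPM), the only E(spl) ratio of the 4 contrasts in these nuclei whose interval leaves out 1. E(spl)m8-HLH had 16.7, 18.4, 34.5 and 23.2 CPM and E(spl)m6-BFM 16.7, 18.4, 14.4 and 18.6. The others were near the limit, with 2, 3, 3 and 1 UMIs of E(spl)mdelta-HLH, 0, 2, 4 and 2 of E(spl)malpha-BFM, 0, 1, 1 and 1 of E(spl)m2-BFM, 4, 0, 3 and 0 of E(spl)m4-BFM and 1, 0, 0 and 1 of E(spl)m5-HLH. The glial homeobox gene repo was at 194, 235, 282 and 195 CPM, 1.45-fold (1.04 to 2.04) higher in NICD-OE than in control in normoxia. Eaat1, the glutamate transporter gene that defines the driven cells, was at 422, 460.2, 189.7 and 353 CPM, 2.22-fold (1.64 to 3.04) lower in NICD-OE in normoxia, and at 306, 275, 369 and 399.6 CPM in neural progenitor-like nuclei. The marker gene w gave 2, 3, 5 and 4 UMIs in glia-like nuclei. Over all nuclei w was 1.69-fold (1.31 to 2.20) higher in NICD-OE in normoxia and 2.27-fold (1.73 to 3.06) higher in hypoxia, with 93, 66, 180 and 220 UMIs. Over all nuclei N was also 1.49-fold (1.47 to 1.51) and 1.32-fold (1.30 to 1.34) higher in NICD-OE, and progenitor-like nuclei, more frequent there in normoxia, held 4025, 4216, 3979 and 4418 CPM of it. The E(spl) genes over all nuclei were higher in NICD-OE in normoxia, from E(spl)mgamma-HLH 1.31-fold (1.22 to 1.42) to E(spl)mdelta-HLH 1.73-fold (1.38 to 2.19). In hypoxia they ran from E(spl)m2-BFM 1.11-fold (0.906 to 1.38) to E(spl)m8-HLH 1.71-fold (1.48 to 1.98). The exception was E(spl)m6-BFM, 1.22-fold (1.10 to 1.35) and 1.29-fold (1.12 to 1.48) lower. Whether the mix of classes bears on these ratios was not tested.

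**Figure D2:**
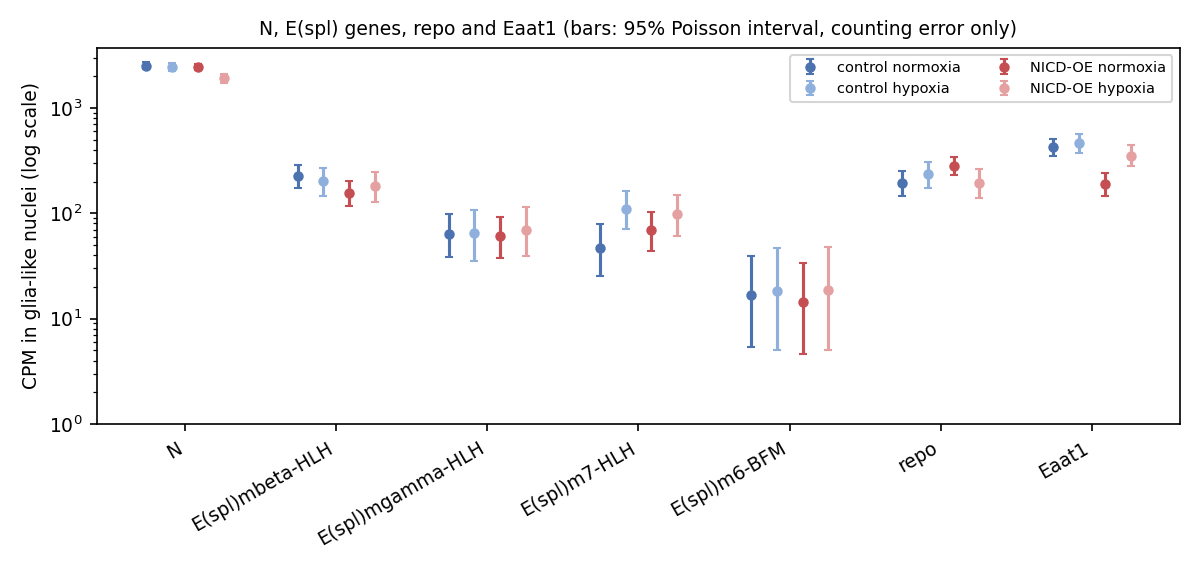
Levels in glia-like nuclei (CPM, log scale on the vertical axis) of N, 4 E(spl) genes, repo and Eaat1 in the 4 libraries, with 95% Poisson intervals as bars. Eaat1 was at 422 CPM in control normoxia and 189.7 CPM in NICD-OE normoxia.

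In control larvae, hypoxia went with more RNA of the secreted metalloprotease gene AdamTS-B in glia-like nuclei (621 (521 to 735) against 167 (124 to 221) CPM) and of Tret1-1, which encodes a trehalose transporter (957 against 392 CPM). Hsp83, the Hsp90 chaperone gene, was higher too (985 against 422 CPM), and fabp, encoding a fatty acid binding protein, was lower (166 against 455 CPM). Ratios of the genes higher in hypoxia were AdamTS-B 3.69-fold (2.67 to 5.24), DIP-lambda 2.87-fold (2.13 to 3.93), Tret1-1 2.44-fold (1.94 to 3.09) and Hsp83 2.33-fold (1.87 to 2.93). Socs36E, which restrains JAK/STAT signalling, was 2.61-fold (1.93 to 3.598) higher, raw, a regulator of JNK signalling, 2.09-fold (1.55 to 2.85), and kek1, an inhibitor of the EGF receptor, 2.23-fold (1.54 to 3.27). Also on this side were CG6357 2.20-fold (1.81 to 2.69), Myo81F 2.11-fold (1.71 to 2.62), CG32512 2.36-fold (1.68 to 3.38), CG46339 2.25-fold (1.57 to 3.27) and CG42673 2.46-fold (1.56 to 4.01). AdamTS-B (FBgn0029791, chromosome X, 5698557 to 5708633, + strand) was counted in 16 normoxic and 22 hypoxic nuclei, with 45.2% of its hypoxic UMIs in 1 nucleus (log2 1.57 without the top nuclei, from 1.88). The optic lobe homeobox gene Vsx1 was at least 12.6-fold lower in hypoxia (6 normoxic nuclei, 1 with 55.8% of its UMIs; at least 5.58-fold without it), and rdo, encoding a leucine-rich repeat protein, 8.79-fold (3.91 to 30.5). The ecdysone-induced factor gene Eip93F was 2.83-fold (2.20 to 3.74) lower, fabp 2.72-fold (1.89 to 4.09) and Sirup, needed to assemble succinate dehydrogenase, 2.49-fold (1.73 to 3.73). Further genes lower in hypoxia were tyn 4.77-fold (2.62 to 10.4), asRNA:CR44894 3.40-fold (2.31 to 5.29) and Gapdh1 3.70-fold (1.99 to 8.10). The ribosomal protein genes RpS10b, RpL7A, RpL37-1 and RpL35 were lower as well, by 3.11-fold (2.11 to 4.86), 2.38-fold (1.77 to 3.29), 2.65-fold (1.73 to 4.32) and 2.60-fold (1.66 to 4.33). A single nucleus of control normoxia had 21111 UMIs, against 6400 at most in the others, and held 36.4% of the ribosomal protein UMIs of that library's glia-like nuclei. The top nucleus there held 31.5% of the UMIs of RpS10b, 41.5% of RpL7A, 33.3% of RpL37-1, 26.4% of RpL35, 43.1% of Gapdh1 and 39.1% of Sirup. Without the nucleus richest in ribosomal proteins in each library, log2 ratios were -1.23, -0.63, -1.15 and -1.15 for the ribosomal genes in that order (from -1.64, -1.25, -1.41 and -1.38) and -0.70 for Sirup (from -1.32). Gapdh1 was at -1.21 without its top nuclei (from -1.89). The single nucleus of control normoxia also held 876 of the 1516 mitochondrial UMIs from which the ambient share of control normoxia is estimated, 23.9% with it and 10.8% without it. The part of the control normoxia level that ambient RNA would bring depends on it (without it in parentheses): fabp 91.5% (49.7%), RpS10b 109% (67.3%), RpL7A 89.2% (64.6%), RpL37-1 98.9% (62.8%), RpL35 78.9% (45.4%) and Gapdh1 62.0% (46.1%). With whole glia-like clusters, 12 of 34 named genes moved by over 1.5 times and DIP-lambda (log2 -0.69) and CG46339 (-0.28) turned, with Tret1-1 at 0.20. Removing the expected doublets turned raw (-0.34) and left Hsp83 at 0.22 and RpL7A at -0.04.

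Notch targets as a list stood higher in control hypoxia, with a median log2 ratio of 0.62 (percentile 99.9; 5 of 10 measured members at least 1.5-fold higher, 0 lower), although E(spl)mbeta-HLH was 1.10-fold lower. Genes of the Notch pathway had a median of -0.11 (percentile 33.4, 1 higher and 1 lower), with Delta, a ligand of Notch, 1.14-fold higher and mam, its coactivator, 1.22-fold lower. The hypoxia response list was level at 0.01 (percentile 48.8; 1 of 8 measured members at least 1.5-fold higher, 1 lower), with scyl 1.15-fold higher, sima, the HIF alpha gene, 1.10-fold higher and chrb 1.27-fold lower. The lipid list was lower, at -0.28 (percentile 2.12; 5 of 55 measured members at least 1.5-fold higher, 18 lower). Within it fatty acid oxidation was at -0.80 (percentile 0.140, 0 higher and 10 lower) of 14, with whd, the mitochondrial carnitine palmitoyltransferase gene, 1.81-fold lower and pdgy 1.42-fold. In lipid transport (0.21 (percentile 94.5, 1 higher and 3 lower)) apolpp, a lipoprotein gene, was 1.17-fold higher and Obp44a 2.09-fold lower. Glycolysis was at -0.48 (percentile 0.260, 2 higher and 8 lower) of 17, with Gapdh2 2.38-fold lower against the higher Tret1-1. Respiration was at -0.55 (percentile 0.200, 2 higher and 15 lower) of 32, with sesB, the ADP/ATP carrier gene, 1.73-fold lower and ATPsynbeta 1.45-fold. Ribosomal proteins were at -0.69 (percentile 0, 0 higher and 51 lower) of 82, RpL41 being 1.13-fold higher. Without the nucleus richest in ribosomal proteins in each library these medians shrank, to -0.18 for ribosomal proteins, -0.12 for glycolysis, -0.29 for respiration, -0.47 for fatty acid oxidation and -0.21 for lipid genes. Beside these lists, mitochondrial UMIs were 0.504, 0.249, 0.214 and 0.453% of glia-like UMIs over the 4 libraries, which puts the ambient share at 23.9, 13.3, 10.7 and 22.4%; without the richest nuclei it was 10.8, 12.4, 10.4 and 22.0%. With ambient RNA subtracted the respiration median turned to 0.54, and with the expected doublets removed the glycolysis median turned to 0.07 and the hypoxia response median went to 0.41. Of the control normoxia level ambient RNA would bring, with the richest nucleus and without it in parentheses, sesB 84.6% (46.4%), ATPsynbeta 74.1% (39.5%), Gapdh2 57.4% (54.0%) and Obp44a 128% (56.7%).

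In NICD-OE larvae, hypoxia went with more ImpL2 in glia-like nuclei, a gene for a secreted antagonist of insulin signalling (1747 (1575 to 1933) against 474 (405 to 552) CPM). Gs2, which encodes a glutamine synthetase, and Eaat1 were both higher (469 against 109 CPM; 353 against 189.7 CPM). The extracellular matrix gene tnc (107 against 439.7 CPM) and drl, a receptor for Wnt5 (191 against 483 CPM), were lower. Ratios were ImpL2 3.68-fold (3.06 to 4.45), Gs2 4.26-fold (2.93 to 6.42) and Eaat1 1.86-fold (1.32 to 2.63). The odorant binding protein gene Obp99b was 44.2-fold (20.3 to 152) higher, the Hox gene Ubx 11.1-fold (7.59 to 17.5) and rost 10.6-fold (6.23 to 20.8). Octalpha2R, an octopamine receptor gene, was 4.11-fold (3.11 to 5.53) higher, the carbonic anhydrase gene CAH7 4.30-fold (2.87 to 6.74), the sugar transporter gene pippin 3.53-fold (2.17 to 6.05) and the collagen gene Mp 3.33-fold (2.05 to 5.66). Also higher were CG40470 3.30-fold (2.61 to 4.23) and CG6357 3.28-fold (2.33 to 4.72) and the potassium channel gene SLO2 2.64-fold (2.04 to 3.45). Genes lower in hypoxia began with rdo 17.3-fold (7.94 to 59.1), tnc 4.04-fold (2.64 to 6.68), CG42747 2.69-fold (2.08 to 3.55) and drl 2.51-fold (1.79 to 3.66). Hr4, a nuclear receptor gene of the ecdysone response, was 2.48-fold (1.76 to 3.63) lower, the homeobox gene scro 1.94-fold (1.71 to 2.21) and Tmtc1 2.23-fold (1.74 to 2.92). Long noncoding and other transcripts lower here were lncRNA:CR45919 4.00-fold (2.07 to 9.60), lncRNA:CR44997 1.88-fold (1.73 to 2.03), lncRNA:CR46006 1.97-fold (1.71 to 2.27), lncRNA:CR45388 2.13-fold (1.70 to 2.72) and l(2)41Ab 2.88-fold (1.73 to 5.30). ImpL2 lies at chromosome 3L, 4224006 to 4236147, - strand, and Gs2 at chromosome X, 11422832 to 11430197, + strand. In NICD-OE hypoxia the top nucleus of the gene held 84.7% of the UMIs of Obp99b, 83.2% of Ubx and 87.4% of rost. Without the nucleus that held most of each gene's UMIs, log2 ratios dropped to 3.08 for Obp99b, 0.94 for rost, 2.12 for Ubx and 0.84 for pippin.

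Transmitter uptake genes were higher with hypoxia in NICD-OE, at a median log2 ratio of 0.59 (percentile 98.8; 3 of 6 measured members at least 1.5-fold higher, 1 lower), with Gdh, the glutamate dehydrogenase gene, 1.84-fold higher and nrv2 1.13-fold. Notch targets had a median of 0.29 (percentile 86.7; 2 of 10 measured members at least 1.5-fold higher, 0 lower); hry was 1.24-fold higher, klu 1.20-fold and E(spl)mbeta-HLH 1.17-fold. The Notch pathway was at -0.28 (percentile 4.42, 1 higher and 2 lower), with fng, which modifies Notch by glycosylation, 1.44-fold higher and numb, an inhibitor of Notch, 1.45-fold lower. The hypoxia response list stood at -0.18 (percentile 15.8; 2 of 8 measured members at least 1.5-fold higher, 0 lower), with sima 1.13-fold and chrb 1.498-fold lower. The lipid list was at 0.08 (percentile 74.2; 13 of 55 measured members at least 1.5-fold higher, 7 lower): apolpp was 2.32-fold and the desaturase gene Desat1 1.67-fold higher, and the lipophorin receptor gene LpR2 1.72-fold and Acsl 1.59-fold lower. Fatty acid oxidation was at 0.33 (percentile 93.0, 3 higher and 1 lower) and lipid transport at 0.37 (percentile 97.1, 6 higher and 3 lower). Fat body genes were higher in the same contrast: Fbp1 stood at 26.8, 4.60, 5.75 and 214 CPM in glia-like nuclei, Lsp2 at 83.7, 0, 14.4 and 149 and Lsp1beta at 20.1, 0, 0 and 92.9, with 83.3% of the UMIs of 6 such genes in 1 nucleus of NICD-OE hypoxia. Without the nucleus richest in them in each library the medians were 0.09 for lipid genes, 0.21 for fatty acid oxidation and 0.37 for lipid transport; whether RNA of fat body bears on apolpp and Desat1 was not tested. Glycolysis was at 0.30 (percentile 96.8, 4 higher and 1 lower), led by Pfk, the phosphofructokinase gene, 3.06-fold higher. Respiration was level at -0.05 (percentile 32.7, 5 higher and 4 lower), with ATPsynbeta 1.33-fold higher and Ogdh 1.49-fold lower. Ribosomal proteins were at 0.52 (percentile 100, 30 higher and 1 lower), among them RpLP2 2.16-fold higher. Ambient subtraction turned the glycolysis median to -0.59, and removing the expected doublets took the hypoxia response median to 0.26 and the lipid median to -0.08.

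Between the genotypes in normoxia, glia-like nuclei of NICD-OE held nAChRalpha6, a nicotinic receptor subunit gene, at 787 (697 to 886) against 23.4 (9.42 to 48.3) CPM in control. The adhesion gene Dscam4 was higher as well (836 against 70.3 CPM). The nuclear factor gene dac (57.5 against 378 CPM), Gs2 (109 against 522 CPM) and Eip93F (216 against 957 CPM) were lower in NICD-OE. Ratios of the genes higher in NICD-OE were nAChRalpha6 31.4-fold (16.1 to 84.4), Dscam4 11.6-fold (7.64 to 19.5) and tnc 4.62-fold (3.12 to 7.29). IP3K2, encoding a kinase of inositol trisphosphate, was 6.01-fold (2.89 to 16.6) higher, Cipc 4.84-fold (2.69 to 10.2) (log2 1.64 without its top nuclei, from 2.28), the sodium channel gene NaCP60E 3.64-fold (2.07 to 7.24) and the adhesion gene Fas3 2.09-fold (1.77 to 2.49). Also higher were mthl3 2.93-fold (2.20 to 4.00), CG42747 2.60-fold (2.08 to 3.30), tei 3.12-fold (1.98 to 5.27), drl 2.52-fold (1.86 to 3.48) and lncRNA:cherub 2.08-fold (1.81 to 2.39). nAChRalpha6 was counted in 4 control and 83 NICD-OE nuclei and Dscam4 in 14 and 91. In neuron-like nuclei nAChRalpha6 stood at 4363, 4617, 2448 and 2947 CPM and in ambient RNA at 452, 655, 222 and 274. Genes lower in NICD-OE were led by dac 6.45-fold (4.07 to 11.2), Eip93F 4.42-fold (3.43 to 5.81) and Gs2 4.73-fold (3.34 to 7.01). The carbonic anhydrase gene CAH1 was 2.78-fold (2.23 to 3.50) lower, the nucleoside transporter gene Ent2 3.61-fold (2.19 to 6.41) (log2 -0.94 without its top nucleus, from -1.85), the TRP channel gene wtrw 3.56-fold (2.07 to 6.69), MRP, a gene for an ABC transporter, 3.02-fold (1.88 to 5.12) and pippin 3.83-fold (2.43 to 6.41). The rest were CG6357 3.89-fold (2.84 to 5.48), CG40470 2.93-fold (2.33 to 3.73), scaf 3.49-fold (2.03 to 6.57) and Sirup 2.65-fold (1.93 to 3.71), with Sirup at log2 -0.80 without the nucleus richest in ribosomal proteins in each library (from -1.41). nAChRalpha6 is FBgn0032151, chromosome 2L, 9793317 to 9886250, - strand, and dac is FBgn0005677, chromosome 2L, 16466512 to 16485998, - strand. With whole glia-like clusters 12 of 37 named genes moved by over 1.5 times and tei turned (log2 -0.45), with IP3K2 at 0.13. With the expected doublets removed tnc (-0.57), RpLP2 (0.08) and RpS10b (0.21) turned.

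**Figure D3:**
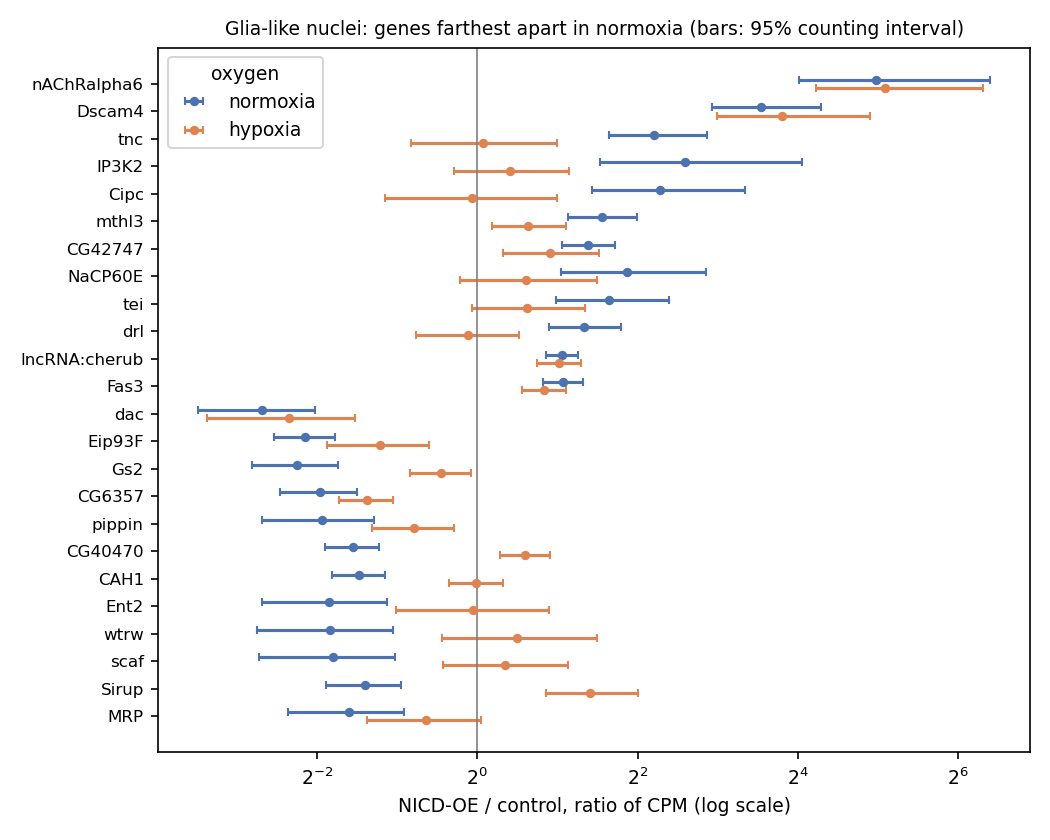
Ratio of NICD-OE to control in glia-like nuclei (log scale on the horizontal axis) of 24 genes far apart in normoxia, in normoxia (blue) and hypoxia (orange), with 95% counting intervals as bars. nAChRalpha6 was 31.4-fold higher in normoxia and 34.1-fold higher in hypoxia.

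Uptake of transmitters was the list lowest in NICD-OE normoxia, at a median log2 ratio of -1.24 (percentile 0; 0 of 6 measured members at least 1.5-fold higher, 5 lower), with Gs2 and Eaat1 as above, Gdh 1.965-fold lower and nrv2 1.46-fold higher. Notch targets were at 0.21 (percentile 81.4; 3 of 10 measured members at least 1.5-fold higher, 1 lower), hry 1.21-fold higher and E(spl)mbeta-HLH 1.44-fold lower. In the Notch pathway (-0.10 (percentile 16.5, 2 higher and 1 lower)) numb was 2.34-fold higher and mam 1.08-fold lower. The hypoxia response was at -0.28 (percentile 2.77; 0 of 8 measured members at least 1.5-fold higher, 2 lower), with bnl, an FGF gene, 1.93-fold lower. Lipid genes were at -0.22 (percentile 0.835; 4 of 55 measured members at least 1.5-fold higher, 16 lower). LpR2 was 1.73-fold higher and Acsl 1.38-fold, while pdgy was 2.06-fold and apolpp 1.73-fold lower. Fatty acid oxidation was at -0.77 (percentile 0.0100, 0 higher and 9 lower), with Hnf4, a nuclear receptor gene of fat use, 1.58-fold lower. Glycolysis was at -0.63 (percentile 0.0100, 1 higher and 9 lower), Gapdh1 being 2.23-fold and Gapdh2 2.38-fold lower. Lipid transport stood at -0.23 (percentile 7.76, 1 higher and 4 lower), respiration at -0.02 (percentile 36.1, 6 higher and 6 lower) with Ogdh 1.70-fold higher, and ribosomal proteins at -0.45 (percentile 0, 1 higher and 24 lower) with RpLP2 1.93-fold lower. Without the nucleus richest in ribosomal proteins in each library the medians were 0.00 for ribosomal proteins, -0.25 for glycolysis, -0.19 for fatty acid oxidation, 0.18 for respiration and -0.12 for lipid genes, and RpLP2 was at -0.17. The ribosomal median turned positive with equal weight per nucleus (0.08) and with at most 2% mitochondrial UMIs (0.13). With ambient RNA subtracted the lipid median (0.01) and that of lipid transport (0.00) turned. With the expected doublets removed the medians of Notch targets (-0.21), the hypoxia response (0.29), lipid genes (0.02), glycolysis (0.17) and ribosomal proteins (0.29) turned.

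Between the genotypes in hypoxia, nAChRalpha6 and Dscam4 were again higher in glia-like nuclei of NICD-OE (1487 against 41.4 CPM; 739 against 50.6 CPM) and dac again lower (60.4 against 318 CPM). ImpL2, whose product binds insulin-like peptides, was higher too (1747 against 736 CPM), and daw, an activin-type ligand gene, was lower (112 against 349.8 CPM). Ratios were nAChRalpha6 34.1-fold (18.7 to 79.2), Dscam4 14.0-fold (7.94 to 29.8) and ImpL2 2.37-fold (1.97 to 2.87) higher. Ubx, at 196 UMIs against 0, was at least 66.0-fold higher, Obp99b 33.8-fold (14.5 to 141) and rost 9.18-fold (4.99 to 20.6). Single nuclei of NICD-OE hypoxia held most of these UMIs, as given above (Ubx was counted in 3 nuclei). Without the top nucleus of the gene Ubx was at least 11.1-fold higher, and log2 ratios were 2.76 for Obp99b and 1.85 for rost (from 5.08 and 3.20). The virus-induced gene vir-1 was 5.11-fold (3.04 to 9.59) higher, the anion exchanger gene Ae2 3.33-fold (2.16 to 5.46), the homeobox gene dve 2.72-fold (2.00 to 3.798) and trol, encoding perlecan, 2.34-fold (1.98 to 2.79). RpS10b was 3.46-fold (2.31 to 5.45) and CG14989 3.41-fold (2.03 to 6.25) higher, though ambient RNA at its estimated share would bring 112% and 133% of their levels in NICD-OE hypoxia. Genes lower in NICD-OE were led by dac 5.10-fold (2.88 to 10.4), lncRNA:CR46006 2.75-fold (2.39 to 3.17) and CG6357 2.60-fold (2.07 to 3.31). The integrin gene mew was 2.68-fold (2.00 to 3.68) lower, daw 3.09-fold (1.959 to 5.19), how, which encodes an RNA-binding protein of glia, 1.964-fold (1.66 to 2.33) and Rnf11, a ubiquitin ligase gene, 2.08-fold (1.64 to 2.68). Others lower were Myo81F 2.34-fold (1.84 to 3.02), sprt 2.97-fold (1.80 to 5.29), CG32512 2.61-fold (1.77 to 4.00), CG43658 2.00-fold (1.76 to 2.29) and Liprin-gamma 2.45-fold (1.76 to 3.51). Dscam4 is FBgn0263219, chromosome 3L, 8238647 to 8282398, + strand. Whole glia-like clusters moved 11 of 33 named genes by over 1.5 times, Obp99b to log2 2.62 and CG14989 to 0.55 among them, and removing the expected doublets moved trol to 4.54.

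In hypoxia the ribosomal proteins stood higher in NICD-OE, at a median log2 ratio of 0.74 (percentile 100; 54 of 82 measured members at least 1.5-fold higher, 0 lower), with RpL34b 2.63-fold higher. Respiration was at 0.56 (percentile 98.8, 16 higher and 2 lower), sesB 1.55-fold and ATPsynbeta 1.55-fold higher, and glycolysis at 0.38 (percentile 94.2, 7 higher and 3 lower), with Pfk 1.97-fold and the aldolase gene Ald1 1.41-fold higher and Tret1-1 1.79-fold lower. Notch targets were at -0.12 (percentile 15.8; 0 of 10 measured members at least 1.5-fold higher, 0 lower). The Notch pathway was at -0.13 (percentile 16.1, 2 higher and 1 lower), fng 1.61-fold higher and Delta 1.35-fold lower. The hypoxia response was at -0.29 (percentile 7.37; 0 of 8 measured members at least 1.5-fold higher, 1 lower), with sima 1.17-fold and scyl 1.29-fold lower. Lipid genes were at 0.18 (percentile 70.1; 17 of 55 measured members at least 1.5-fold higher, 5 lower): Desat1 was 2.23-fold and Obp44a 2.22-fold higher and LRP1 1.27-fold lower, beside the fat body genes given above. Fatty acid oxidation was at 0.73 (percentile 99.3, 7 higher and 2 lower) with Hnf4 1.21-fold lower, lipid transport at -0.03 (percentile 30.04, 3 higher and 2 lower) with fabp 1.92-fold higher, and transmitter uptake at -0.27 (percentile 6.53, 0 higher and 1 lower) with Gs2 1.37-fold lower. With ambient RNA subtracted, the medians of respiration (-0.05) and glycolysis (-0.60) turned negative. Ambient RNA would bring RpL34b 84.4%, sesB 74.4%, ATPsynbeta 52.7%, Ald1 74.3%, Desat1 52.2%, fabp 92.7%, Obp44a 102% and Calr 103% of the NICD-OE hypoxia levels. The expected doublets removed took the medians of lipid genes to -0.11 and fatty acid oxidation to -0.72 (-0.13 with list members of at least 100 UMIs), and whole clusters took transmitter uptake to 0.61.

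**Figure D4:**
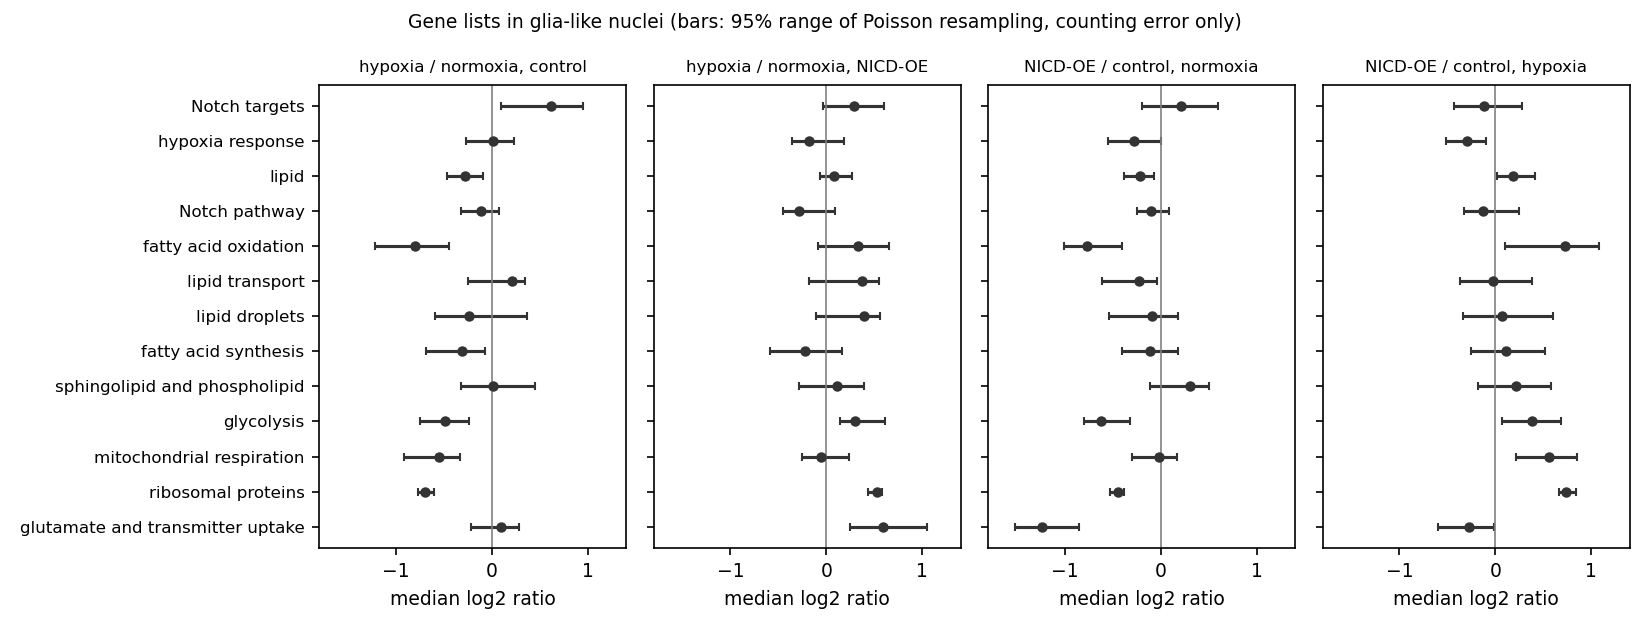
Median log2 ratio (horizontal axis) of 13 gene lists in glia-like nuclei for the 4 contrasts, with 95% ranges of Poisson resampling as bars. Ribosomal proteins were at -0.69 (-0.77 to -0.60) for hypoxia in control and 0.52 (0.43 to 0.58) for hypoxia in NICD-OE; without the nucleus richest in these genes in each library they were at -0.18 and 0.52, and under ambient subtraction the respiration and glycolysis medians turn in several contrasts.

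The response to hypoxia itself differed between the genotypes for some glial genes; these differences of log2 ratios (NICD-OE less control) were not tested. Ubx had at least 6.24, a bound, resting on 28, 0, 28 and 196 UMIs in 1, 0, 5 and 3 nuclei; 1 nucleus held all of them in control normoxia and 83.2% in NICD-OE hypoxia. Vsx1, like Ubx at 0 in control hypoxia (52, 0, 22 and 9 UMIs), had at least 3.11. Obp99b had 5.01, with 84.7% of its NICD-OE hypoxia UMIs in 1 nucleus, Sirup 2.81, CG40470 2.15 and Octalpha2R 2.08. With glial sub-clusters standardised the control contrast of CG40470 turned from log2 -0.42 to 0.40. RpS10b and RpLP2, genes of the ribosome, had 2.29 and 2.22, and 1 nucleus held 47.5% of the RpLP2 UMIs, 31.5% of the RpS10b UMIs and 39.1% of the Sirup UMIs of control normoxia. On the other side were Cipc at -2.35 and tnc at -2.13, both lower with hypoxia in NICD-OE (2.64-fold and 4.04-fold), and IP3K2 at -2.18, higher with hypoxia mainly in control (5.78-fold). CG32512 had -1.58, lncRNA:CR46006 -1.49, lncRNA:CR45388 -1.36, Myo81F -1.33 and scro -1.03.

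Other gene lists in glia-like nuclei are given as median log2 ratios for hypoxia in control, hypoxia in NICD-OE, NICD-OE in normoxia and NICD-OE in hypoxia. Heat shock genes had -0.12, 0.23, 0.03 and 0.09, with Hsp83 2.02-fold higher in NICD-OE hypoxia than normoxia and the small heat shock gene Hsp27 1.53-fold lower in control hypoxia. Redox genes had -0.29, 0.30, -0.11 and 0.40, with GstS1, a glutathione transferase gene, 3.14-fold higher in NICD-OE in hypoxia. The unfolded protein response with ATF4 had -0.43, 0.28, -0.06 and 0.54, Calr, the calreticulin gene, being 1.63-fold lower with hypoxia in control and 1.63-fold higher in NICD-OE in hypoxia. Immune genes had 1.10, 0.88, 0.36 and -0.03, and 1.20, 0.18, 0.94 and -0.08 without the nucleus richest in fat body genes in each library, with Socs36E 2.05-fold higher in NICD-OE in normoxia. Ecdysone and insulin genes had -0.01, -0.04, -0.21 and -0.20, with foxo 2.04-fold higher with hypoxia in NICD-OE and Eip75B 1.18-fold higher with hypoxia in control. Fatty acid synthesis had -0.31, -0.22, -0.12 and 0.11, lipid droplets -0.23, 0.39, -0.09 and 0.07 with the perilipin gene Lsd-2 1.964-fold higher in NICD-OE in hypoxia, and sphingolipids with phospholipids 0.01, 0.11, 0.30 and 0.22 with the ceramide synthase gene schlank 1.37-fold higher there. Cell cycle genes had -0.17, -0.06, 0.09 and 0.21, cell death -0.22, -0.20, 0.38 and -0.34 and autophagy -0.30, 0.08, -0.01 and 0.42, in which Lamp1 was 1.79-fold higher in NICD-OE in hypoxia. Neuronal transmitter genes had -0.48, 0.26, -0.73 and 1.25, synapse genes 0.12, -0.14, 0.10 and 0.01 with Snap25, a SNARE gene, 1.68-fold higher in NICD-OE in hypoxia, and dosage compensation 0.57, 0.01, 0.31 and -0.51. Without the nucleus richest in ribosomal proteins in each library, heat shock genes in control came to 0.05 and redox genes to -0.18 for hypoxia, and redox genes to 0.02 for NICD-OE in normoxia.

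In neuron-like nuclei hypoxia went with more RNA of heat shock genes, which also differed between the genotypes (below). Peptide genes are given singly, as no list of them was made and single nuclei held much of the UMIs of several. In control, the peptide genes Orcokinin and AstA were higher in hypoxia (14.0 against 2.60 CPM; 15.6 against 3.20 CPM), as were Hsp70Bc and Hsp70Ab, close copies of a chaperone gene. In NICD-OE the peptide genes FMRFa, Lk, Pdf, AstA and Capa were higher (22.6 against 0.989 CPM for FMRFa, 17.7 against 2.62 CPM for Pdf). In control Lk was higher too, 2.98-fold, but FMRFa, Pdf and Capa were lower with hypoxia, by 1.99-fold, 6.14-fold and 3.91-fold, with 82.2%, 58.1% and 32.0% of their control normoxia UMIs in 1 nucleus. Ratios in control were Orcokinin 5.33-fold (3.91 to 7.53), AstA 4.83-fold (3.64 to 6.58), Hsp70Bc 6.46-fold (3.5997 to 13.5) and Hsp70Ab 3.68-fold (2.79 to 4.94). The salivary glue genes had Sgs5 8.83-fold (7.10 to 11.2) and Sgs4 4.66-fold (3.77 to 5.84), but ambient RNA would bring 217% and 216% of their control hypoxia levels. Such parts exceed the levels themselves, so the estimated ambient share is too high for these genes. Ratios in NICD-OE were FMRFa 22.4-fold (14.7 to 37.8), Lk 8.76-fold (6.06 to 13.5), Pdf 6.71-fold (5.07 to 9.18), AstA 6.04-fold (4.68 to 8.04), Capa 5.997-fold (4.56 to 8.15) and CG15784 8.04-fold (4.99 to 14.5). Lower in control hypoxia were the yolk protein genes Yp1 42.0-fold (26.5 to 76.1), Yp2 22.3-fold (14.5 to 38.3) and Yp3 34.2-fold (19.8 to 72.2), the rhodopsin gene ninaE at least 37.4-fold, Arr2, the arrestin gene, at least 30.5-fold and CG14645 at least 31.4-fold. In ambient RNA Yp1 stood at 818, 0.346, 0 and 0 CPM, and ambient RNA would bring Yp1 131%, Yp2 130.3%, Yp3 155%, ninaE 67.5%, Arr2 60.5% and CG14645 113% of the control normoxia levels. Lower in NICD-OE hypoxia were LysD 12.2-fold (5.72 to 36.9), Peritrophin-15a 4.73-fold (2.73 to 9.18), Dph1 2.62-fold (2.29 to 3.01), spok 2.42-fold (2.09 to 2.83), E(spl)m6-BFM 2.48-fold (2.07 to 3.00) and Traf4 2.38-fold (2.02 to 2.82). Of their NICD-OE normoxia levels ambient RNA would bring LysD 123%, Peritrophin-15a 130.0% and spok 104%. In NICD-OE hypoxia its part would be Lk 59.8%, Pdf 61.7%, Capa 64.4% and CG15784 64.0%. Whether the shift in the cluster led by CG4577, given above, bears on the peptide genes was not tested. In NICD-OE hypoxia the top nucleus of the gene held 43.7% of the UMIs of FMRFa, 31.5% of Lk, 35.5% of Pdf, 32.0% of AstA and 49.1% of Capa, and in control hypoxia 71.8% of Orcokinin and 40.7% of AstA. Ambient subtraction took the log2 ratio of Orcokinin with hypoxia in control to 5.28 and equal weight per nucleus to 1.25.

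Heat shock genes as a list were higher with hypoxia in neuron-like nuclei, at a median log2 ratio of 0.29 (percentile 100; 7 of 18 measured members at least 1.5-fold higher, 1 lower) in control and 0.22 (percentile 99.5, 6 higher and 0 lower) in NICD-OE. The hypoxia response list was at 0.12 (percentile 98.6; 5 of 15 measured members at least 1.5-fold higher, 0 lower) and 0.28 (percentile 99.8, 4 higher and 0 lower). Cell cycle genes were at -0.39 (percentile 0.0100; 0 of 24 measured members at least 1.5-fold higher, 8 lower) and -0.23 (percentile 0, 0 higher and 1 lower). Respiration was at -0.42 (percentile 0, 0 higher and 11 lower) in control and -0.01 (percentile 16.5, 0 higher and 1 lower) in NICD-OE, glycolysis at -0.20 (percentile 1.05, 0 higher and 3 lower) and 0.35 (percentile 99.99, 3 higher and 0 lower), and Notch targets at 0.13 (percentile 97.6, 3 higher and 4 lower) and -0.24 (percentile 0.0800, 1 higher and 3 lower). Heat shock genes were also higher in NICD-OE than in control, at 0.22 (0.14 to 0.27) in normoxia and 0.35 (0.31 to 0.40) in hypoxia. Differences of a similar size to those with hypoxia thus occurred between libraries of the same oxygen condition.

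Neuron-like nuclei of the genotypes differed most in genes that were close to 0 in one line. Tektin-C, a microtubule gene of cilia, was at 64.6 against 0.387 CPM in normoxia, and mthl8, of the methuselah receptor family, at 22.7 against 0.166 CPM. The genes mfr and Culd went the other way (0.0494 against 36.6 CPM; 0.544 against 41.7 CPM), and N itself was 1.66-fold (1.57 to 1.76) higher in NICD-OE in normoxia and 1.52-fold (1.43 to 1.62) in hypoxia. Ambient RNA would bring 38.3%, 62.9%, 41.0% and 64.2% of N in these nuclei. Other genes higher in NICD-OE in normoxia were Tektin-C 156-fold (80.9 to 417), mthl8 118-fold (46.6 to 667), lncRNA:CR43766 89.5-fold (48.0 to 221), lncRNA:CR40469 39.7-fold (19.5 to 118), lncRNA:CR45450 58.2-fold (15.2 to 3466) and lncRNA:CR44914 19.7-fold (10.7 to 45.9). In hypoxia they were Tektin-C 224-fold (98.0 to 924), mthl8 at least 74.2-fold, lncRNA:CR40469 78.3-fold (31.0 to 444), lncRNA:CR44914 55.0-fold (28.4 to 147), lncRNA:CR43766 38.3-fold (23.8 to 70.9) and Col4a1 28.6-fold (19.6 to 45.2), Col4a1 being a collagen gene of hemocytes. Ambient RNA would bring 114% and 148% of lncRNA:CR40469 in NICD-OE. Lower in NICD-OE in normoxia were mfr 494-fold (132 to 29288), CG9701 at least 62.2-fold, Culd 73.4-fold (42.6 to 154), ppk20 149-fold (39.6 to 8865), Yp1 63.8-fold (38.5 to 125) and bond 59.7-fold (38.2 to 106), and in hypoxia Cyp4p1 59.9-fold (34.7 to 126), Cyp4p2 28.0-fold (20.2 to 41.1), CG9701 37.7-fold (21.7 to 79.6), mfr 28.8-fold (19.7 to 45.8), bond 26.1-fold (19.1 to 37.7) and Culd 22.4-fold (15.1 to 36.1). Notch targets were at 0.33 (percentile 99.5; 5 of 20 measured members at least 1.5-fold higher, 0 lower) in normoxia and 0.27 (percentile 66.8, 6 higher and 1 lower) in hypoxia, and turned with ambient RNA subtracted (-0.04 and -0.22). Cell cycle genes were at 0.30 (percentile 99.9; 6 of 24 measured members at least 1.5-fold higher, 0 lower) and 0.59 (percentile 100, 12 higher and 0 lower), glycolysis at 0.07 (percentile 68.5, 0 higher and 1 lower) and 0.75 (percentile 100, 13 higher and 0 lower), and respiration at 0.00 (percentile 7.47, 2 higher and 1 lower) and 0.42 (percentile 100, 12 higher and 0 lower).

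In neural progenitor-like nuclei the Notch target E(spl)mgamma-HLH was higher with hypoxia in both genotypes, 1.51-fold (1.24 to 1.84) in control and 1.94-fold (1.69 to 2.23) in NICD-OE (167, 251, 189.6 and 368 CPM). E(spl)mbeta-HLH (80.4, 106, 95.6 and 156 CPM) and E(spl)m8-HLH (29.8, 50.5, 41.3 and 74.8 CPM) went the same way. The transcription factor genes cas and svp were lower with hypoxia in NICD-OE, cas by 2.63-fold (2.30 to 3.03) and svp by 2.75-fold (1.963 to 4.04). Eaat1 was 1.21-fold (1.08 to 1.35) higher in NICD-OE in normoxia and 1.45-fold (1.22 to 1.74) in hypoxia. In control, hypoxia also went with more gsb-n 3.50-fold (2.29 to 5.45), lncRNA:CR33938 3.36-fold (2.60 to 4.39), lncRNA:CR31386 2.89-fold (2.41 to 3.46), CG15646 2.74-fold (2.34 to 3.21), CG13907 2.99-fold (2.07 to 4.36) and Sgs5 15.8-fold (7.56 to 43.8) and less Yp1 at least 14.3-fold, Yp2 9.12-fold (2.98 to 95.7), Yp3 20.3-fold (5.26 to 1212), Lsp1gamma at least 8.10-fold, dpr6 18.3-fold (4.72 to 1094) and side-II 5.34-fold (2.53 to 16.1). In NICD-OE it went with more Obp99b 9.44-fold (6.36 to 14.8), CG31145 5.35-fold (3.38 to 8.85), Hsp26 2.77-fold (2.20 to 3.50), side-II 2.99-fold (2.13 to 4.21), CG31221 2.48-fold (1.97 to 3.12) and Sh 2.40-fold (1.93 to 2.98) and less rk 5.22-fold (2.48 to 15.8), l(2)41Ab 3.27-fold (2.46 to 4.51), ato 4.09-fold (2.01 to 11.2) and beat-IIb 4.89-fold (2.01 to 20.7). NICD-OE had more CG9008 61.6-fold (16.3 to 3663), mthl8 at least 11.1-fold, Tektin-C 27.9-fold (7.20 to 1667), rk 21.1-fold (7.03 to 220.2), lncRNA:CR40469 26.7-fold (6.86 to 1591) and CG31697 8.32-fold (3.43 to 35.2) and less Yp1 45.3-fold (17.5 to 259), Yp2 33.5-fold (10.9 to 351), Yp3 at least 37.0-fold, Cyp4p2 53.7-fold (13.7 to 3210.2), Lsp1gamma 7.19-fold (3.94 to 15.2) and Sec31 3.44-fold (2.54 to 4.76) in normoxia. In hypoxia it had more CG31145 at least 13.2-fold, Obp99b 17.4-fold (7.43 to 72.9), Dscam4 4.91-fold (3.90 to 6.34), side-II 8.20-fold (3.88 to 24.8), wb 5.26-fold (3.49 to 8.56) and CG7781 6.68-fold (2.94 to 23.3) and less gsb-n 4.23-fold (2.55 to 7.56), Rnf11 2.25-fold (1.98 to 2.57), svp 2.96-fold (1.98 to 4.55), Tmtc1 2.79-fold (1.9601 to 4.05), lncRNA:CR31386 2.16-fold (1.79 to 2.62) and CG9514 2.54-fold (1.78 to 3.67). Of the higher of these levels ambient RNA would bring Yp1 106%, Yp2 126%, Yp3 102% and Lsp1gamma 65.1% in control normoxia, 137% of Sgs5 in control hypoxia, and Obp99b 78.6%, CG31221 92.4%, side-II 52.4%, CG7781 132% and lncRNA:CR40469 117% in NICD-OE hypoxia. Its subtraction turned Yp3 with hypoxia in control to log2 1.68 and CG31221 with hypoxia in NICD-OE to -0.25. Notch targets were at 0.39 (percentile 99.5; 5 of 16 measured members at least 1.5-fold higher, 3 lower) for hypoxia in control and 0.59 (percentile 99.98, 8 higher and 1 lower) in NICD-OE, and at 0.28 (percentile 92.8, 4 higher and 1 lower) and 0.62 (percentile 98.6, 8 higher and 0 lower) between the genotypes in normoxia and hypoxia. Glycolysis had -0.23, 0.44, 0.06 and 0.83 and respiration -0.35, 0.13, 0.06 and 0.66 in the same order. With ambient RNA subtracted the hypoxia medians in NICD-OE turned to -0.18 and -0.12, those of NICD-OE in hypoxia to -0.50 and -0.14, and that of respiration with hypoxia in control to 0.10.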

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

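The 2 tests on adult genes and the test of Notch activity in glia were written before their results, and the other tests in this part were chosen only after the result was seen. In glia-like nuclei several hypoxia contrasts went one way in control and the other way in NICD-OE, and these differences were not tested. The glycolysis list had medians of -0.48 in control and 0.30 in NICD-OE, 0.79 apart, with the control median at -0.12 without the nucleus richest in ribosomal proteins in each library. The opposition ended with ambient RNA subtracted (NICD-OE -0.59) and with the expected doublets removed (control 0.07). Ubx differed by at least 6.24, a bound because it had 0 UMIs in control hypoxia (8.85 with 0.5 count added to each sum). Its UMIs lay in 1, 0, 5 and 3 nuclei, 1 of which held 83.2% of the NICD-OE hypoxia UMIs. Sirup differed by 2.81 (-1.32 and 1.495) and CG40470 by 2.15 (-0.42 and 1.72). With glial sub-clusters standardised the control contrast of CG40470 turned to 0.40. RpLP2 differed by 2.22 and RpS10b by 2.29, and 1 control normoxia nucleus held 39.1% of the Sirup, 47.5% of the RpLP2 and 31.5% of the RpS10b UMIs, while lncRNA:CR46006 had -1.49, higher with hypoxia in control and lower in NICD-OE.

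Barcodes of 10 to 100 UMIs, outside the comparisons of the report, held transcripts in control normoxia that were near 0 in the other 3 libraries: the yolk protein genes Yp1 818, Yp2 509 and Yp3 549.6 CPM, the rhodopsin gene ninaE 68.3, CG34324 153, CG34220 104, CG14645 96.0, CG17108 60.7 and CG4716 58.5 CPM, and 9.95% of the nuclei of that library lay in clusters found almost only there. If nuclei of adult flies were the source, adult genes not looked at before should stand at least 10-fold higher in those nuclei than in the other libraries; the median over 11 genes was 5.00-fold, 4 of them above 10-fold (Arr1 54.7 against 0.0304 CPM, trpl 41.4 against 0.243) and Rh4 lower, which leaves it open. Against ambient RNA of the same library those genes summed to a ratio of 2.77 (2.61 to 2.93), above the bound of 2 set for excluding ambient RNA, but rdgB, at 307 CPM in the other libraries, makes up most of the sum, and without it the ratio is 1.68, so ambient RNA cannot be told apart either. The settings of calling and clustering are argued against, since the share stayed at 8.80% or more over the other 7 settings. A difference in age or tissue make-up may lie behind the pattern and was not tested otherwise.

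Ribosomal protein genes had opposite hypoxia contrasts in glia-like nuclei, -0.69 in control and 0.52 in NICD-OE, 1.22 apart, and a first test by subtraction of ambient RNA was void, as it left 79.3% of members at 0. A single nucleus of control normoxia, with 36.4% of the ribosomal UMIs of that library's glia-like nuclei, may account for most of the control contrast, since without the nucleus richest in these genes in each library its median was -0.18, but a single nucleus is argued against for NICD-OE, whose median was then 0.52. Nuclei of few UMIs are argued against as the whole cause, since with at least 1000 UMIs the difference was 1.18, and without the richest nuclei 0.56, against 0.70 with nuclei of fewer UMIs kept. Ambient RNA at its mitochondrial share would bring 105, 97.4, 67.8 and 114.9% of the ribosomal UMIs over the 4 libraries, and 69.9, 96.0, 68.1 and 116% without those nuclei, so a different share of ambient RNA cannot be told apart. A difference that all classes share stays open, because subtraction left 51.2% of members at 0 in neuron-like nuclei, where the difference without subtraction was 0.45, and a response of glia that differs between the genotypes was not tested apart from these.

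In neuron-like nuclei 16 genes were over 4-fold higher and 11 over 4-fold lower in NICD-OE in both oxygen conditions, Tektin-C and mfr among them, although the driver was aimed at glia. Ambient RNA from other cells is argued against for most of them, since it would bring a median 6.25% of their level (lncRNA:CR40469 was the exception at 148%). A difference of genetic background between the fly lines could explain them, but the test cannot decide it. In nuclei outside the neuron-like and glia-like classes all 27 differed in the same direction, by a median 4.87 on the log2 scale. Those nuclei include the 7 unnamed clusters with neuron markers raised, so they can repeat the neuron result. In glia-like nuclei, signed by the direction in neuron-like nuclei, Nha1 (4.26), lncRNA:CR40469 (4.63), lncRNA:CR43766 (5.80) and Cyp4p2 (4.00) kept it. Col4a1 (-0.19) and Ugt317A1 (-0.20) went the other way. Notch activity in glia stays open: over the 6 genes measured there the log2 difference less that in neuron-like nuclei was -1.12 in the median, under the bound of 0.5 set before for excluding it, but the range of -4.42 to 1.06 holds that bound. Of these genes lncRNA:CR43766 (chromosome 2L, 9848200 to 9849069) lies within nAChRalpha6, and whether background bears on both was not tested.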

How the results depend on the processing

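The settings chosen only after the data were seen are the removal of the expected doublets, whole glia-like clusters, shares without one-library clusters, ratios without the top nucleus of the gene, and values without the nucleus richest in ribosomal proteins or in fat body genes in each library; the other tests of processing were planned. In every setting run, progenitor-like shares were lower and neuron-like shares higher with hypoxia in both genotypes, and NICD-OE hypoxia had the lowest glia-like share. The Notch target median in glia-like nuclei stayed positive for hypoxia in control (0.15 to 0.87) and in NICD-OE (0.07 to 0.39). The lipid median stayed negative for hypoxia in control (-0.49 to -0.13), and the hypoxia response median for NICD-OE in hypoxia (-0.41 to -0.22). The other main medians took both signs. No paired analysis was possible because each group has 1 library, and the shared number 1 only names the samples.

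Main values that moved beyond their interval and values that turned follow, with list medians and gene ratios on the log2 scale; the cause was not tested. At least 1000 UMIs gave glia-like shares of 0.980% in control normoxia, 0.881% in NICD-OE normoxia and 0.616% in NICD-OE hypoxia, a neuron-like share of 52.6% in NICD-OE hypoxia, a neural progenitor-like share of 3.58% in NICD-OE hypoxia. At least 500 UMIs gave neuron-like shares of 51.9% in control normoxia, 60.7% in control hypoxia, 52.0% in NICD-OE normoxia and 57.8% in NICD-OE hypoxia. At most 2% mitochondrial UMIs gave neuron-like shares of 45.9% in NICD-OE normoxia and 51.9% in NICD-OE hypoxia, for NICD-OE in normoxia in glia-like nuclei ribosomal proteins 0.13, RpLP2 0.19. Keeping doublets gave a neuron-like share of 52.6% in NICD-OE hypoxia. No centring gave neuron-like shares of 48.4% in control normoxia, 58.0% in control hypoxia and 46.5% in NICD-OE normoxia. Resolution 2 gave neuron-like shares of 42.4% in control normoxia, 50.5% in control hypoxia, 41.8% in NICD-OE normoxia and 48.1% in NICD-OE hypoxia, for hypoxia in NICD-OE in glia-like nuclei lipid 0.28. Removal of the expected doublets gave glia-like shares of 0.987% in control normoxia, 0.781% in control hypoxia, 0.776% in NICD-OE normoxia and 0.320% in NICD-OE hypoxia, neuron-like shares of 53.1% in control normoxia, 63.0% in control hypoxia, 51.8% in NICD-OE normoxia and 58.7% in NICD-OE hypoxia, neural progenitor-like shares of 6.74% in control normoxia, 9.61% in NICD-OE normoxia and 4.68% in NICD-OE hypoxia. It also gave for hypoxia in control in glia-like nuclei hypoxia response 0.41, lipid -0.49, glycolysis 0.068, raw -0.34, for hypoxia in NICD-OE in glia-like nuclei hypoxia response 0.26, lipid -0.080, for NICD-OE in normoxia in glia-like nuclei Notch targets -0.21, hypoxia response 0.29, lipid 0.017, glycolysis 0.17, ribosomal proteins 0.29, RpLP2 0.081, RpS10b 0.21, tnc -0.57. Further values there were for NICD-OE in hypoxia in glia-like nuclei lipid -0.11, fatty acid oxidation -0.72. Whole glia-like clusters gave glia-like shares of 2.27% in control normoxia, 1.69% in control hypoxia, 1.82% in NICD-OE normoxia and 1.39% in NICD-OE hypoxia, for hypoxia in control in glia-like nuclei CG46339 -0.28, DIP-lambda -0.69, for NICD-OE in normoxia in glia-like nuclei lipid -0.41, tei -0.45. It also gave for NICD-OE in hypoxia in glia-like nuclei transmitter uptake 0.61. Leaving out one-library clusters gave a neuron-like share of 52.2% in control normoxia, a neural progenitor-like share of 6.88% in control normoxia. Subtracting ambient RNA gave for hypoxia in control in glia-like nuclei respiration 0.54, for hypoxia in NICD-OE in glia-like nuclei glycolysis -0.59, for NICD-OE in normoxia in glia-like nuclei lipid 0.0094, lipid transport 0.0020. It also gave for NICD-OE in hypoxia in glia-like nuclei glycolysis -0.60, respiration -0.053, for hypoxia in NICD-OE in neuron-like nuclei ribosomal proteins -0.83, for NICD-OE in normoxia in neuron-like nuclei Notch targets -0.041, ribosomal proteins -0.11. Further values there were for NICD-OE in hypoxia in neuron-like nuclei Notch targets -0.22, for hypoxia in control in neural progenitor-like nuclei respiration 0.10, Yp3 1.68, for hypoxia in NICD-OE in neural progenitor-like nuclei glycolysis -0.18, respiration -0.12, ribosomal proteins -0.42, CG31221 -0.25. The rest were for NICD-OE in hypoxia in neural progenitor-like nuclei glycolysis -0.50, respiration -0.14, ribosomal proteins -0.82. Equal weight per nucleus gave for NICD-OE in normoxia in glia-like nuclei ribosomal proteins 0.077, RpS10b 0.076. List members of at least 100 UMIs gave for NICD-OE in normoxia in glia-like nuclei lipid -0.059, for NICD-OE in hypoxia in glia-like nuclei fatty acid oxidation -0.13. Median-of-ratios size factors gave for NICD-OE in hypoxia in neural progenitor-like nuclei lipid -0.020. Standardised glial sub-clusters gave for hypoxia in control in glia-like nuclei CG40470 0.40, for NICD-OE in hypoxia in glia-like nuclei CG40470 -0.20. Leaving out the nucleus richest in ribosomal proteins in each library gave for NICD-OE in normoxia in glia-like nuclei ribosomal proteins 0.0048.

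Of 2349 named gene ratios over all settings, 2078 stayed within their interval, 258 moved beyond it and 13 turned; of 1146 list medians these were 992, 124 and 30, and of 100 shares 64, 36 and 0. Some values were left out, by a filter chosen after the data were seen: gene ratios with both groups under 50 UMIs in a setting, gene ratios with either group at 0 after ambient subtraction, and list medians with at least 50% of the members at 0 after it in either group; without it 360 of 2550 gene ratios moved and 45 turned, and 127 and 33 of 1152 list medians. Most gene ratios without a value came from removing the expected doublets (69 in glia-like nuclei) and from subtracting ambient RNA (22 in glia-like, 28 in neuron-like and 17 in progenitor-like nuclei), and subtraction left 4 ribosomal medians in glia-like and 2 in neuron-like nuclei without one. Median-of-ratios factors shifted the median of all genes by -0.10, -0.16 and -0.17 for NICD-OE in hypoxia in glia-, neuron- and progenitor-like nuclei, and ambient subtraction by 0.17 for hypoxia in control, -0.12 for hypoxia in NICD-OE and 0.15 for NICD-OE in normoxia in glia-like nuclei and -0.14 for NICD-OE in hypoxia in progenitor-like nuclei.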

Other observations

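No tests were run for the values in this part, so none was chosen after a result was seen. Neuroepithelium-like nuclei, with markers such as tll and Optix, made up 0.814, 0.435, 1.41 and 0.728% of nuclei (107, 44, 240 and 123). Hemocyte-like nuclei made up 0.228, 0.227, 0.674 and 0.515%. Col4a1, a collagen gene expressed in hemocytes and fat body, stood at 7.63, 5.12, 43.9 and 50.2 CPM over all nuclei. The ecdysone-induced gene Eip93F was at 2275, 2259, 1481 and 1163 CPM and br, a gene of the same hormone response, at 6734, 6975, 7534 and 7153. The Hox genes Antp and Ubx are given above.

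Genes of other larval organs were found in nuclei and more so in ambient RNA. The salivary glue genes Sgs4 and Sgs5 were at 6.65, 29.8, 3.13 and 18.2 and 7.11, 48.7, 2.10 and 15.8 CPM over all nuclei and at 84.2, 745, 19.0 and 228 and 156, 1189, 23.8 and 205 CPM in ambient RNA. Obp99b was at 6.18, 11.4, 10.5 and 58.8 CPM in nuclei and 133, 182, 149.9 and 628 in ambient RNA. The fat body genes Lsp2 and Fbp1 were at 25.6, 8.60, 8.70 and 25.5 and 6.92, 4.80, 7.19 and 22.3 CPM in nuclei. The RNAs lncRNA:roX1 and lncRNA:roX2, made in males, were at 1909, 2759.9, 2735 and 2889 and 188, 250.02, 262 and 224 CPM, and Sxl, the switch gene of sex determination, at 1578, 1347, 1303 and 1322 CPM; the sex make-up of the libraries is not given in the sources used here.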
